A study of Mus musculus with 4 samples.

How the data were processed

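RNA was sequenced from mouse embryonic fibroblasts (MEFs) of 2 genotypes, wild type (WT) and Dnmt3l knockout (Dnmt3l-KO), with 2 libraries per genotype. Per the labels' protocols, the fibroblast lines came from embryos of day 13.5 to 14.5 of Dnmt3l heterozygote intercrosses on a C57BL/6 background, were at passage 4, and were sequenced from RNA depleted of ribosomal RNA, primed with random primers. Nothing in the labels says that the libraries of a genotype came from separate embryos. The p-values therefore measure the spread between these libraries, which may in part be technical.

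Per the submitters' processing notes, the tools were TopHat2 2.0.12, Cufflinks 2.2.1, eXpress 1.4.1 and DESeq2 1.8.0, and the genome build was mm10; the role of each tool is not given in the sources used here. Per the file headers, the deposited table holds an estimated count and an FPKM value for each RefSeq transcript in each library. The deposited estimated counts were whole numbers. Per the file headers, it also holds the authors' own comparison, with a mean signal over all libraries, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value for each transcript. How reads that match several transcripts or gene copies were divided is not given in the sources used here, so every estimated count of a gene with a near-identical copy depends on a step that could not be examined.

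The table held 116415 transcripts, each with a gene symbol in its description. Counts were summed per symbol, which gave 36846 symbols, of which 21138 had a count above 0 in some library. Positions were taken from the RefSeq gene table of GRCm38, the same build as mm10, which held 29553 of the symbols. Sequence identity between copies was measured with BLAST 2.17.0 on GENCODE transcripts of that build, over alignments that covered at least 80% of the copy. Total counts ranged from 40681328 to 51465395 per library. A count of 3 in a library was used as the floor where a group had no counts. It came to 0.0601 to 0.0719 CPM, the counts scaled to a common library total, and it covers counting error only, since reads amplified by PCR are not independent molecules.

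The comparison was Dnmt3l-KO minus WT, tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust estimation, TMM normalization) on the 14760 symbols that passed edgeR's expression filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM library sizes. Standard errors of log2 fold changes were derived from the F statistic. Of the 42 gene lists fixed before the data were examined, the 39 with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over those lists. Named genes were also chosen by a rule fixed before the data were examined. They were Dnmt3l, the genes with the largest fold changes among those past the threshold or, where fewer than 5 passed in a direction, the 5 with the smallest p, up to 4 members with the smallest p of each list described, Xist and 4 Y-linked genes, and any gene above 5% of a library's counts. Atp6v0c, Gnptg, Snrpf, Pou5f1, Mlycd, Acta1 and the genes said to be so in the text were named outside that rule, after their values had been seen. Values of some genes are not reported here.

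The gene test was tested on simulated counts drawn for the 14760 genes with the libraries' own depths and the fitted dispersion trend. Of 50 genes changed at each size, it recovered 26% at 1.5-fold, 54% at 2-fold, 96% at 4-fold and all 50 at 8-fold, with 2 unchanged genes among 140 calls. Of 30 simulated lists of unchanged, independently drawn genes, camera called 0, and it called the list that was raised. Those simulations hold no correlation between genes, and each gene lies on the dispersion trend, without spread around it. They also reached 140 calls, against 3 in the data, and with fewer calls the adjustment asks for a smaller p. The simulated recovery is therefore higher than the test can reach in these data.

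Alternatives covered other normalizations, a DESeq2 1.42.0 Wald test, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, other filters, transcripts as features, the replicate number as a block, leaving out the X and Y chromosomes or each library in turn, and other list tests. Summing near-identical copies (LOC102641579 and LOC102638183 included, by their descriptions alone) and correcting each library for transcript length and GC content (loess, span 0.4) were added after the data had been seen.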

Results

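Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts (MEFs) that were wild type (WT, 2 libraries) or lacked Dnmt3l (Dnmt3l-KO, 2 libraries). Dnmt3l encodes a cofactor of the de novo DNA methyltransferases that is itself without catalytic activity. The study asked which genes differ between fibroblasts used as donor cells for nuclear transfer, where the knockout cells were reported to do better. Total counts were 47776612 and 41049869 in the WT libraries and 51465395 and 40681328 in the Dnmt3l-KO libraries. The 45S ribosomal RNA precursor Rn45s was the most abundant gene in each library, with 6.64% and 6.86% of the counts in WT and 7.08% and 7.18% in Dnmt3l-KO.

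Dnmt3l (chromosome 10, 78042287 to 78063622, GRCm38) was close to undetected in both genotypes. The WT libraries held 6 counts and 1 count over its 6 transcripts, and both Dnmt3l-KO libraries held 0. These values lie around the floor of 3 counts per library, so no fold change is given, and the gene was not tested. They do not check the genotype labels, since the wild-type fibroblasts themselves hardly expressed the gene. Xist, the RNA that coats the inactive X chromosome, had 17770 and 13773 counts in WT and 14163 and 19686 counts in Dnmt3l-KO, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 4 libraries. All 4 libraries therefore carried a female expression pattern, and sex did not differ between the genotypes.

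Across 14760 genes, 3 passed the test between the genotypes, and all 3 belong to families of near-identical gene copies. The pseudogene Gm9855 and the predicted gene Gm6139 were higher in Dnmt3l-KO. Tdg, which encodes thymine DNA glycosylase, an enzyme of base excision repair that acts in active DNA demethylation, was lower. Tdg (chromosome 10, 82629814 to 82650799) fell from 29.6 ± 2.60 CPM in WT to 0.933 ± 0.101 CPM in Dnmt3l-KO (mean ± SD, n = 2 each), a 31.8-fold lower level, with a log2 fold change of -4.99 ± 0.16 (SE) and an adjusted p of 0.0044 in edgeR's quasi-likelihood test. Gm9855 (chromosome 10, 42052558 to 42055453) had 0 counts in both WT libraries and 1602 and 1336 counts in Dnmt3l-KO, which is at least 472-fold higher against the floor (edgeR, adjusted p = 0.0055). Its sequence was 99.25% identical to that of Tdg over 1194 bases. The sum of Tdg and Gm9855 was 29.6 ± 2.60 CPM in WT and 33.0 CPM in each Dnmt3l-KO library, with a log2 fold change of 0.15 ± 0.11 (SE, edgeR, adjusted p = 0.999). The separate values of Tdg and Gm9855 are therefore uncertain, and their joint level did not differ beyond the spread.

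Gm6139 (chromosome 5, 129622949 to 129623892) was 98.87% identical over 882 bases to Rps2, the gene of a small-subunit ribosomal protein, and to further copies that were not summed with it, such as Rps2-ps10 at 98.98%. Gm6139 had 0.137 ± 0.0435 CPM in WT and 395.1 ± 30.3 CPM in Dnmt3l-KO, a log2 fold change of 11.48 ± 0.21 (SE, edgeR, adjusted p = 0.00052). Rps2 itself (chromosome 17, 24718121 to 24721927) had a log2 fold change of -0.44, which did not pass (edgeR, adjusted p = 0.999). Summed, Rps2 and Gm6139 had 2499 ± 113 CPM in WT and 2241 ± 36.6 CPM in Dnmt3l-KO, a log2 fold change of -0.16 ± 0.11 (SE, edgeR, adjusted p = 0.999). With these copies and 3 further pairs summed, edgeR called 0 genes, with 603 genes at an unadjusted p under 0.05. The pairs were chosen after their values had been seen. LOC102641579 with Gnptg and LOC102638183 with Snrpf were paired by their descriptions alone, without a sequence comparison. The sum of Snrpf and LOC102638183 still had a log2 fold change of -0.44 ± 0.23 (SE). The value of Gm6139 is likewise uncertain, and its sum with Rps2 says little about it. A rise of Gm6139 alone over unchanged Rps2 would have moved the sum by 0.21 on the log2 scale, above the -0.16 ± 0.11 measured. A rise beside a lower Rps2 is not excluded, since the ribosomal protein genes were lower as a list (median -0.17).

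**Figure D1:**
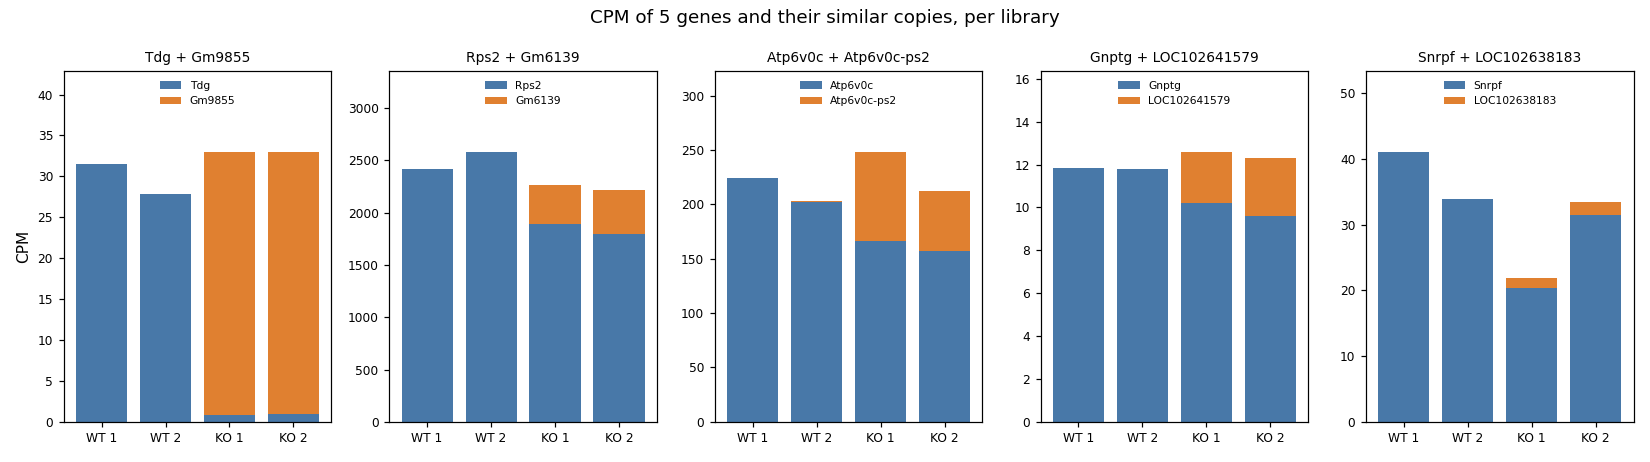
Library-scaled counts (CPM, linear axis from 0) of 5 genes and of a similar copy of each, stacked, in each of the 4 libraries. The sum of Tdg and Gm9855 lies between 27.8 and 33.0 CPM in each library, and 97.2% of its Dnmt3l-KO counts are assigned to Gm9855.

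The 3 genes ranked next upward did not pass in the main edgeR fit. Each was a copy of another gene or was only described as similar to one. Atp6v0c-ps2, a pseudogene 99.78% identical over 465 bases to the proton pump subunit gene Atp6v0c, had 14 and 3 counts in WT and 4063 and 2300 counts in Dnmt3l-KO (edgeR, adjusted p = 0.051). LOC102641579, described in the files as similar to Gnptg, and LOC102638183, described as similar to Snrpf, had 0 counts in both WT libraries. They had 119 and 113 counts, and 75 and 83 counts, in Dnmt3l-KO, at least 37.5-fold and 25.7-fold above the floor (edgeR, adjusted p = 0.245 and 0.51). Downward, the next in rank were Snora78, an H/ACA small nucleolar RNA encoded within Rps2 (48.2 ± 1.25 against 20.4 ± 1.3 CPM, adjusted p = 0.197), and the uncharacterized LOC102642140 (37.9 ± 6.05 against 9.34 ± 1.74 CPM, adjusted p = 0.245). The histone gene Hist1h2ad (24.9 ± 3.10 against 9.60 ± 0.143 CPM, adjusted p = 0.245) and the zinc finger gene Zfp52 (25.5 ± 0.513 against 14.4 ± 0.415 CPM, adjusted p = 0.623) followed; all 4 are WT against Dnmt3l-KO means ± SD with edgeR's adjusted p, and none passed in edgeR. DESeq2's Wald test called all 7 of these genes, with the smallest adjusted p for Atp6v0c-ps2 (1.5e-19) and the largest for Zfp52 (0.0024). Limma on log2(FPKM + 1) values called 5 of the 7, all but Hist1h2ad and Zfp52, and edgeR with no filter 5, all but Atp6v0c-ps2 and Zfp52. Atp6v0c-ps2, close to the threshold, also passed in edgeR in 9 of 14 other settings (adjusted p from 0.00815 to 0.221 over the 14), among them without Dnmt3l-KO replicate 1 or 2 (adjusted p = 0.0495 and 0.032).

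Beyond the copies, no single gene separated the genotypes in this test. At an unadjusted p under 0.05 there were 612 genes, 345 higher and 267 lower in Dnmt3l-KO. Both Dnmt3l-KO libraries lay outside the WT range on the same side in 32.8% of the genes, where chance alone gives 33.3%. The count of 3 moved with the tool and the libraries. DESeq2's Wald test called 31 of the 17040 genes its own filter kept, limma-voom called the same 3 among the same 14760 genes, and edgeR called 2, 4, 6 and 5 genes without WT replicate 1, WT replicate 2, Dnmt3l-KO replicate 1 and Dnmt3l-KO replicate 2; Tdg was lost without WT replicate 1, where 1 WT library remains, with its log2 fold change still at -4.90 (adjusted p = 0.056).

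Of the regulators of DNA methylation, 20 of 21 measured genes did not pass, and Tdg, whose value is uncertain as above, was the exception, also when adjusted over the list alone. Dnmt1, the maintenance methyltransferase, had 105.5 ± 6.89 CPM in WT and 109.2 ± 4.21 CPM in Dnmt3l-KO. Dnmt3a, a de novo methyltransferase, had 24.7 ± 2.43 and 25.9 ± 5.99 CPM, and Dnmt3b, the other, had 0.877 ± 0.291 and 0.837 ± 0.0342 CPM. These 3 were named after their values were seen. Camera gave the list an adjusted p of 0.785, with a median log2 fold change of 0.02 and, because of Tdg, a mean of -0.22. Mbd3, a subunit of the NuRD corepressor, had a log2 fold change of 0.38 ± 0.11, and Hells, a chromatin remodeller needed for DNA methylation, one of -0.30 ± 0.11 (SE, edgeR, adjusted p = 0.999 for both). Among histone deacetylases and their cofactors, 0 of 20 genes passed in edgeR, with 1 at an unadjusted p under 0.05. Of 29 genes in the Polycomb group list 0 passed in edgeR. Kdm6b, a demethylase in that list that opposes Polycomb, was alone at an unadjusted p under 0.05. Of 19 genes of H3K9 methylation and heterochromatin 0 passed, with 0 at that level. DESeq2 called none of these genes other than Tdg.

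Imprinted genes, whose methylation marks are set in the germline with Dnmt3l, were not called as groups by camera. The embryos came from heterozygote intercrosses, so both parents carried a working Dnmt3l allele. These lists therefore do not test a loss of Dnmt3l in the germline. Of 27 paternally expressed genes 0 passed in edgeR or DESeq2, with 3 at an unadjusted p under 0.05, and camera gave an adjusted p of 0.319 for the list, whose median log2 fold change was 0.04. The lowest p belonged to Dlk1, which encodes a Notch-related membrane protein (16.8 ± 3.10 CPM in WT, 25.6 ± 1.5 CPM in Dnmt3l-KO), Igf2, a fetal growth factor (609.9 ± 94.4 and 880.4 ± 50.8 CPM), and Peg10 (82.8 ± 8.51 and 100.5 ± 0.397 CPM), each with an adjusted p of 0.999 in edgeR. The summed level of the paternally expressed genes, in which Igf2 was the most abundant, was 1495 ± 32.2 CPM in WT and 1848 ± 144 CPM in Dnmt3l-KO, a ratio of 1.24 that was not tested. Of 19 maternally expressed genes 0 passed, with 0 at an unadjusted p under 0.05, and camera gave an adjusted p of 0.844 at a median of 0.02.

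By camera with its preset correlation, 10 of 39 gene lists were called between the genotypes, 7 lower and 3 higher in Dnmt3l-KO. All of the 10 but pluripotency were also called when the libraries were split into pairs that mix the genotypes. A call alone therefore does not show an effect of genotype. None of the 10 kept its call with an estimated correlation (adjusted p = 0.937 for each), and fry called 0 lists. With 4 libraries, both tests have little from which to estimate the spread and could hardly have called any list. Over all lists tested, their smallest adjusted p was 0.937 (camera, estimated correlation) and 0.975 (fry). Their outcome therefore says little for or against a call. The small nucleolar RNAs, which guide the modification and processing of ribosomal RNA, were the furthest apart. Of 18 measured, 17 had a negative fold change and 13 lay below both WT libraries in both Dnmt3l-KO libraries. For a single gene chance gives 16.7% per direction. The members come from the same 4 libraries and move together (estimated correlation 0.22), so their number is not a test of the list. Their median log2 fold change was -0.90 (-0.58 in Dnmt3l-KO replicate 1 and -1.04 in replicate 2 against the WT mean; camera, adjusted p = 8.5e-13; adjusted p = 0.937 with an estimated correlation). In edgeR 0 of them passed over all genes and 4 passed when adjusted over the list alone, while DESeq2's Wald test called 4 over all genes, Snora73a, Snora73b, Snora74a and Snora78. Snora73a had 1444 ± 312 CPM in WT and 686 ± 0.782 CPM in Dnmt3l-KO, and Snora74a had 509 ± 14.3 and 321 ± 22.9 CPM (edgeR, adjusted p = 0.966 for both over all genes; DESeq2, adjusted p = 1.3e-05 and 0.0011). Copies such as Snora73a and Snora73b may share reads. The summed level of the list, most of it from Snora73a, Snora73b (1321 ± 460 and 573 ± 109 CPM) and Snora74a, was 3701 ± 815 CPM in WT and 1829 ± 206 CPM in Dnmt3l-KO, a ratio of 2.02. The list kept its camera call with each library left out, at a median of -0.52 without Dnmt3l-KO replicate 2, and under a correction for transcript length and GC content, at -0.44.

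The replication-dependent histone genes, which supply histones in S phase and whose messages lack poly(A) tails, had negative fold changes in 59 of 64 members. Their median log2 fold change was -0.39 (-0.53 and -0.16 in the Dnmt3l-KO libraries; camera, adjusted p = 2.5e-12; adjusted p = 0.937 with an estimated correlation). In edgeR 0 passed over all genes and 3 when adjusted over the list alone, while DESeq2's Wald test called 3 over all genes, Hist1h2ad, Hist1h2bb and Hist1h3h. Hist1h3h had 56.7 ± 5.58 CPM in WT and 27.6 ± 5.05 CPM in Dnmt3l-KO, and Hist1h2bb had 148.6 ± 16.2 and 82.4 ± 10.1 CPM (edgeR, adjusted p = 0.966 for both; DESeq2, adjusted p = 0.00016 and 0.00061). Histone genes are near-identical to each other, and their summed level, 4790 ± 792 CPM in WT and 3873 ± 615 CPM in Dnmt3l-KO, overlapped between single libraries of the groups, at 4231 CPM in WT replicate 1 and 4308 CPM in Dnmt3l-KO replicate 2. The call was kept with each library left out, at a median of -0.15 without Dnmt3l-KO replicate 1 and -0.19 without WT replicate 2, and under the length and GC correction, at -0.25.

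Cytosolic ribosomal protein genes were lower in 71 of 83 members, 54 of them below both WT libraries in both Dnmt3l-KO libraries, with a median log2 fold change of -0.17 (camera, adjusted p = 1.8e-10). Rps29 had 504 ± 35.7 CPM in WT and 351 ± 40.7 CPM in Dnmt3l-KO, and Rps21 had 469 ± 64.8 and 340.1 ± 18.8 CPM. Nuclear-encoded genes of oxidative phosphorylation were lower in 55 of 69 members with a median of -0.12 (camera, adjusted p = 6.6e-06), as in Uqcrh of complex III (191 ± 8.16 and 142.9 ± 10.9 CPM) and Ndufa2 of complex I (68.5 ± 0.228 and 53.9 ± 2.52 CPM). DNA replication genes were lower in 27 of 30 members with a median of -0.14 (camera, adjusted p = 0.00054), among them the helicase subunit Mcm6 (95.1 ± 0.139 and 79.3 ± 1.41 CPM). No member of these 3 lists passed in DESeq2 over all genes, or in edgeR over all genes or when adjusted over the list alone, and each list had an adjusted p of 0.937 with an estimated correlation. The length and GC correction ended the oxidative phosphorylation call (median -0.048, camera, adjusted p = 0.185) and brought the ribosomal protein median to -0.085 with its call kept; on log2(FPKM + 1) values the oxidative phosphorylation and DNA replication medians were -0.070 and -0.085, both called. The oxidative phosphorylation median was -0.22 without Dnmt3l-KO replicate 1 and its call was lost without replicate 2 (-0.067, adjusted p = 0.261), and the DNA replication call was lost without that library (-0.074, adjusted p = 0.154) or without WT replicate 2 (-0.095, adjusted p = 0.365).

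For interferon response and mitosis genes, the Dnmt3l-KO libraries lay on opposite sides of the WT mean. The WT libraries were apart in the same direction. The median log2 difference, replicate 2 minus replicate 1, was 0.58 in WT and 0.55 in Dnmt3l-KO for interferon response. For mitosis it was 0.24 in WT and 0.47 in Dnmt3l-KO. Interferon response genes had a median of -0.71 in Dnmt3l-KO replicate 1 and 0.05 in replicate 2 (overall -0.31, 24 of 26 members negative; camera, adjusted p = 0.00036). Mitosis genes had medians of -0.38 and 0.08 (overall -0.17, 27 of 30 negative; camera, adjusted p = 0.012). With an estimated correlation the adjusted p was 0.937 for both. Neither list was called without Dnmt3l-KO replicate 1 (adjusted p = 0.696 for interferon response and 0.25 for mitosis) or without WT replicate 2 (0.298 and 0.867). Without Dnmt3l-KO replicate 1 the interferon median was 0.05, opposite in sign to the test, and the mitosis median and test both turned, at 0.08. Without WT replicate 1 and without Dnmt3l-KO replicate 2 the medians were -0.60 and -0.71 for interferon response and -0.26 and -0.38 for mitosis, and without WT replicate 2 they were -0.087 and -0.040. The interferon call was also lost in limma on log2(FPKM + 1) and log2(FPKM + 0.1) values, at medians of -0.063 and -0.11 (camera, adjusted p = 0.161 and 0.166), while the mitosis call was kept there, at -0.11 and -0.12.

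The 3 lists that were higher were Hox genes, pluripotency genes and markers of macrophages and leukocytes. Hox genes, which record position along the body axis, were higher in 32 of 37 members, with a median log2 fold change of 0.18 (camera, adjusted p = 0.00093), as in Hoxc10 (4.03 ± 0.181 and 6.42 ± 0.988 CPM) and Hoxc9 (2.40 ± 0.273 and 4.02 ± 0.885 CPM). Of the pluripotency list 10 of 27 genes were measured and 9 were higher, with a median of 0.32 (camera, adjusted p = 0.0028). The members with the smallest p were Myc, Klf4, Klf2 and Klf5, transcription factors that fibroblasts also express. Myc had 29.2 ± 0.607 CPM in WT and 41.0 ± 8.80 CPM in Dnmt3l-KO, and Klf4 had 47.2 ± 1.12 and 58.2 ± 5.50 CPM. Pou5f1, a core factor of pluripotency, had 4 counts over both WT libraries and 2 over both Dnmt3l-KO libraries. Nanog and Sox2, further core factors, were named after their values were seen. Nanog had 18 counts over both WT libraries and 17 over both Dnmt3l-KO libraries. Sox2 was expressed, with 182 and 313 counts in WT and 252 and 407 counts in Dnmt3l-KO. Macrophage and leukocyte markers had a median of 0.31 (camera, adjusted p = 0.01) at group means under 1 CPM in both genotypes for C1qa, C1qb, C1qc and Tyrobp. No member of the 3 lists passed in edgeR or DESeq2, and each list had an adjusted p of 0.937 with an estimated correlation. All 3 calls were lost without Dnmt3l-KO replicate 1 (medians of 0.14, 0.20 and 0.22, camera, adjusted p = 0.696, 0.397 and 0.194), and the pluripotency and macrophage calls also without WT replicate 2 (medians of 0.27 and 0.0046, adjusted p = 0.051 and 0.977). The pluripotency call was lost with no filter on low counts (0.27, adjusted p = 0.104) and the macrophage call with a stricter filter (0.20, adjusted p = 0.749), and the Hox median was 0.46 without Dnmt3l-KO replicate 2 and the macrophage median 0.62 without WT replicate 1.

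**Figure D2:**
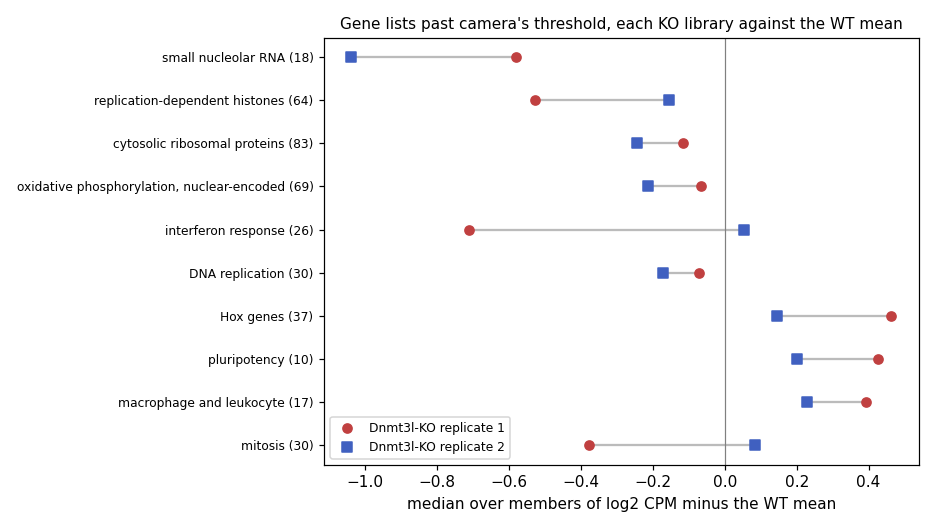
Median over each list's measured members (their number in brackets) of log2 CPM minus the WT mean, for each Dnmt3l-KO library. In 8 of the 10 lists both libraries lie on the same side of 0, and for interferon response and mitosis they lie on opposite sides.

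The Dnmt3l-KO libraries differed from each other more than the WT libraries did. Among 12490 genes with a mean of at least 1 CPM, 581 were over 2-fold apart between the Dnmt3l-KO libraries and 145 between the WT libraries, while 55 were over 2-fold apart between the group means. The first principal component, with 50.8% of the variance, ran from Dnmt3l-KO replicate 1 (-28.1) to replicate 2 (26.2), with the WT libraries at -3.82 and 5.70, and the second, with 32.1%, parted the genotypes. Fibroblast markers were higher in Dnmt3l-KO replicate 2 than in replicate 1 in 27 of 30 genes, with a median log2 difference of 0.62. All 23 measured cholesterol synthesis genes (median 0.49) and all 30 mitosis genes (median 0.47) were higher in replicate 2. Between the WT libraries the mitosis genes were also higher in replicate 2 (median 0.24). There the medians of cholesterol synthesis genes and fibroblast markers were 0.06 and -0.06. The following genes were chosen after their values were seen. The collagen gene Col3a1 had 190.2 and 894.6 CPM, the fibrillin gene Fbn2 30.8 and 232 CPM and the growth factor receptor gene Pdgfra 17.2 and 65.4 CPM in Dnmt3l-KO replicates 1 and 2. Ankrd1, a target of YAP signalling, went the other way, with 99.1 and 28.0 CPM. With 1 library on each side, these differences have no replicate check.

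**Figure D3:**
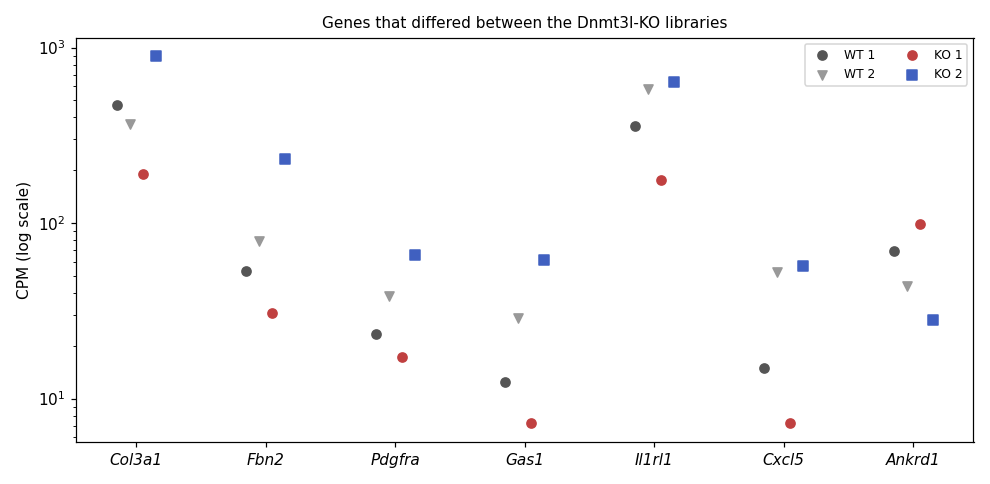
Library-scaled counts (CPM, log axis) of 7 genes in each of the 4 libraries, each point a single library. The Dnmt3l-KO libraries lie at opposite ends of the range for each of these genes, with Col3a1 at 190.2 CPM in replicate 1 and 894.6 CPM in replicate 2.

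In the authors' deposited table, which compares transcripts, 124 transcripts of 119 genes had an adjusted p under 0.05, 66 higher and 58 lower in Dnmt3l-KO. Summed per gene, 3 of the 119 genes passed in edgeR and 27 had an unadjusted p under 0.05. The median absolute log2 fold change was 1.38 for the transcripts in the authors' deposited table and 0.13 for their genes in the edgeR fit. These are unlike measures, since the transcripts were picked by their adjusted p and the fits scale fold changes differently. Gm9855, with the same counts in both, had 6.22 in the authors' comparison and 13.50 in edgeR. Mlycd, which encodes malonyl-CoA decarboxylase, was the gene with transcripts called in both directions. Its summed level was 9.45 ± 0.807 CPM in WT and 9.63 ± 0.693 CPM in Dnmt3l-KO.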

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

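Summing near-identical copies and the length and GC correction were chosen after the data had been seen. Between 8 and 11 lists were called, against 10, under other normalizations, filters, voom, FPKM, the block and both added corrections. The count of 3 genes (2 higher, 1 lower) moved with the tool, the filter and the features. DESeq2's Wald test, on 17040 genes after its own filter, called 31 genes (10 higher, 21 lower), limma-voom 3, edgeR without a filter 8 (4 and 4), limma on log2(FPKM + 1) 8 (5 and 3) and on log2(FPKM + 0.1) 6 (4 and 2). With each transcript its own feature 1 gene was called (1 higher, 0 lower), and with near-identical copies summed 0 (0 and 0), where the copies' own construction shows the cause. The cause was not tested for the others. Leaving out each library in turn gave 2 to 6 genes (2 to 4 higher, 0 to 2 lower) and 5 to 12 lists; the group left with a lone library is assumed there to vary like the other. Tdg, Gm6139 and Gm9855 stayed among the calls under each setting that tested them as genes of their own, except Tdg without WT replicate 1. Camera with an estimated correlation called 0 lists and fry 0, but with 4 libraries neither could readily call a list. With the replicate number as a block, edgeR called 4 genes (Atp6v0c-ps2 added) and camera 11 lists. Deviations of same-numbered libraries correlated at 0.19 across genes, but 2 pairs and the labels do not show that the numbers pair the samples. The value listed for Tdg turned sign with copies summed (0.15), because it then held the counts of Gm9855 as well. Signs also turned for Ehmt2 (-0.017) and Hdac7 (-0.013) under the length and GC correction. The mitosis list turned without Dnmt3l-KO replicate 1 (from -0.38 to 0.082 over the libraries left out). There the median of the interferon list, but not its test, also turned (0.049). For Ehmt2, Hdac7 and these lists the cause was not tested. Of the results for named genes under alternatives, 1359 kept their direction and side of the threshold, 34 gained a call, 1 lost it and 3 turned, and of those for the called lists 161 did, with 36 losing the call. The effective-count alternative was not run, since such counts were not used here. At this depth and spread the simulations recovered 54% of 2-fold changes, so smaller differences were mostly out of reach. That share is too high for these data, since the simulations held many more calls, which eases the adjusted threshold. They also set each gene on the dispersion trend, without spread around it between genes. In the data LOC102642140, 4.06-fold lower in Dnmt3l-KO, did not pass (edgeR, adjusted p = 0.245).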

Other observations

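Genes of development and of reprogramming were examined as further groups. Of 7 measured germline genes, a class that loses repression when DNA methylation is lost, 0 passed in edgeR or DESeq2, with 0 at an unadjusted p under 0.05 and a median log2 fold change of -0.01. The 17 listed genes of the two-cell stage that the table holds had 3 counts in total over the 4 libraries, and none was tested. Fibroblast markers had a median of 0.11 between the genotypes (camera, adjusted p = 0.294), and lists of TGF-beta and YAP targets (0.07, adjusted p = 0.452), senescence (0.02, adjusted p = 0.809) and p53 targets (-0.03, adjusted p = 0.844) were not called.

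Tests of shared reads, of linked strain variants, of other short RNAs, of another cell type and of length and GC content for the DNA replication, interferon response and mitosis lists were chosen only after the results were seen.

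The counts of Tdg in WT had their match in those of its copy Gm9855 in Dnmt3l-KO, with a sum that changed by 0.15 on the log2 scale, as reads shared between near-identical copies would leave it, so a change in the amount of these transcripts is not shown. The sums of Rps2 with Gm6139 and of Atp6v0c with Atp6v0c-ps2 changed by -0.16 ± 0.11 and 0.11 ± 0.12 (SE). A rise of the copy alone, over unchanged Rps2 or Atp6v0c, would have moved them by only 0.21 and 0.40. Rps2 and Atp6v0c may have fallen as well, so shared reads and a rise of these copies cannot be told apart. A candidate reason for reads to switch copies is sequence variants that came with the knockout allele, since Tdg lies 4.59 Mb from Dnmt3l. Within 5 Mb of Dnmt3l, Tdg left out, 6 of 176 tested genes had an unadjusted p under 0.01. That share was 6.72 times that of other autosomal genes (Fisher's exact test, two-sided, p = 0.00039). The test takes neighbouring genes as independent, and of 219 windows of 10 Mb, 4 had a share as high. Within 2 Mb the share was 0 of 63. Of the 6 genes, 3 are zinc finger or predicted genes in a cluster that may share reads. Around Rps2 on chromosome 17, where Atp6v0c (0.55 Mb away) and Gnptg (0.51 Mb away) also lie, the ratio was 2.15 (2 of 173 genes, Fisher's exact test, two-sided, p = 0.243), so variants there stay open, as does any effect of Dnmt3l loss, and read sequences were not analysed here.

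Of the 7 lists that were lower, 4 hold short transcripts, with median lengths from 138 bases (small nucleolar RNA) to 1076.5 (ribosomal proteins) against 3401 for all genes with a sequence, and the DNA replication, interferon response and mitosis genes are longer (3071, 2669 and 3656.5). After a correction of each library for transcript length and GC content, these 3 kept 0.88, 1.04 and 0.836 of their median log2 fold change and their calls, which argues against such a trend as their whole cause, and the lists of short transcripts kept 0.484 (small nucleolar RNA), 0.644 (histones), 0.499 (ribosomal proteins) and 0.411 (oxidative phosphorylation), so that all but the histones met the bound of 0.5 set before the correction was run. The oxidative phosphorylation call ended because its median went from -0.12 to -0.05 while the SD across members stayed at 0.17 (adjusted p = 0.185), which is consistent with a length and GC trend; the other 3 lists of short transcripts stayed called at preset correlation, so how far such a trend accounts for them is open, and 15 of the 28 genes under 200 bases were small nucleolar RNAs themselves, whose own change the correction may have fitted. The other short structural RNAs had a median of -0.42, with negative fold changes in all 13. Of these, 7 lay below both WT libraries in both Dnmt3l-KO libraries. In edgeR 0 passed and 3 had an unadjusted p under 0.05, and DESeq2 called Scarna13. Their fold changes were uneven, from -2.33 for Scarna3a, at 14 counts or fewer per library, to -0.05 for Rpph1, the most abundant. Rnu1b1 and Rnu1b2 had near-equal counts and may share reads. A lower yield of short RNA in the Dnmt3l-KO libraries therefore cannot be told apart from a change in small nucleolar RNA. A biological difference between the genotypes stays among the open explanations, as untested.

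The difference between the Dnmt3l-KO libraries was not a length or GC trend, which explained a share of 0.00916 of its variance across genes. In a test for cells of another type over 5 lists, skeletal muscle genes differed most, with a median of -0.78 (replicate 2 minus replicate 1), and their most abundant member Acta1 had 233.7 and 117.7 CPM in Dnmt3l-KO against 263.2 and 161.2 CPM in WT. The list of cartilage and bone genes, which was not part of that test, had a median of 0.85, with 12 of 17 genes higher in replicate 2. Both medians lie between the bounds set for and against cells of another type in a culture, and fibroblasts themselves express some of these genes, so such cells cannot be told apart from a different growth state of the fibroblasts. No biological explanation was tested, since the labels name no difference between the replicates.

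The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 3 genes (1 of the 3 splits reached that count) and the highest of the others 0. Those 3 are Tdg, Gm9855 and Gm6139, whose values are uncertain. At an unadjusted p under 0.05 in edgeR the real split gave 612 genes and the split by replicate number 1148. The remaining split gave 541. All 3 splits gave at least as many lists as the 10 of the real split, and the highest of the others gave 16, when same-numbered libraries were put together. That split also called the macrophage, mitosis, interferon response, Hox, ribosomal protein, histone and small nucleolar RNA lists. The remaining split also called the macrophage, DNA replication and oxidative phosphorylation lists. Of the lists called in the real split, only pluripotency was called in neither.

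The gene pair Eif3j1 and Eif3j2, subunits of a translation initiation factor, was noticed in the data. Eif3j1 had 46.4 and 40.1 CPM in WT, and 0.1 and 72.8 CPM in Dnmt3l-KO replicates 1 and 2. Eif3j2 had 35.8 and 31.9 CPM in WT, and 70.0 and 1.46 CPM in Dnmt3l-KO. Their sum was 82.2, 72.0, 70.1 and 74.3 CPM, while each gene differed in opposite directions between the Dnmt3l-KO libraries. Whether these paralogs share reads is not shown by such values, and no sequence identity between them is given here.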
